A study of Mus musculus with 5 samples.

How the data were processed

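Kupffer cells of mice were analysed in 5 samples of poly-A RNA, 3 heterozygous for Id3 (replicates 1, 2 and 3) and 2 without Id3 (replicates 2 and 3). Per the labels' protocols, livers were disrupted mechanically through a 100 µm filter in cold PBS, RNA was amplified with the SMART-seq V4 kit, and 10 ng of cDNA went into Kapa libraries with 8 PCR cycles. The values the authors deposited are raw read counts per gene, 1 column per sample, made with HTSeq 0.5.4 per the submitters' processing notes. The same notes name DESeq 1.18.0, R 3.1.2 and the mouse genome build mm9. The aligner, the annotation release and the strand setting are not given in the sources used here. The column names carry a "3w" that the labels do not explain. Gene IDs came with their versions, and 46488 of the 46983 genes (16389 of the 16436 tested) were matched to GENCODE M21 for gene order, transcript length and GC content. Of the 46983 IDs, 37902 carried the same version as in that release, which belongs to a later build than mm9, so the build on which the reads were counted is uncertain. Coordinates of GENCODE M21 were used only to order the genes around Id3 on its chromosome.

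The counts assigned to genes came to 80.9M, 77.7M and 74.8M in the heterozygous and 77.3M and 75.8M in the knockout libraries. The entries that name no gene (reads not aligned, aligned more than once, ambiguous or outside features) were left out of library sizes and tests. They made up 47.0%, 47.5% and 48.6% of everything counted in the heterozygous and 40.0% and 42.8% in the knockout libraries. Reads with several alignments made up 38.3%, 39.3% and 41.0% of the aligned total in the heterozygous and 32.3% and 34.1% in the knockout libraries. Genes with close paralogs are therefore counted in part only. HTSeq can count such a read at each of its alignments, so these shares may exceed the shares of reads. For a gene with 0 counts in a group, a floor of 3 counts per library was used, which is 0.0371 to 0.0401 CPM. Ratios from few counts carry a 95% exact interval of counting error alone. Amplified reads without molecular barcodes vary more than that, so these intervals are too narrow.

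Genotypes were compared as knockout minus heterozygous with all 5 samples and no covariate, in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 16436 genes tested, with no minimum fold. The common biological coefficient of variation was 0.339, with 3 residual and 3.26 prior degrees of freedom. Levels are TMM-normalised CPM with the SD over samples, while marker sums are CPM on library size. The SE of a log2 fold change is its size divided by the square root of the F statistic. With 3 samples against 2, no exact test of a single value can give a p below 0.1, so sums per library are given without a test.

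There were 40 gene lists, written before the data were examined, with markers of other cell types among them, and 39 had the 4 tested members required. Camera (limma 3.58.1) was run on log2 CPM with a prior count of 2 and its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The run with an estimated correlation tests each list on the 3 residual degrees of freedom, so it has little power here. Fry was run beside it. List members were counted as passing over all genes and also adjusted within the list alone. Genes were named by a rule also written before: the Id genes, the 15 highest and 15 lowest by log2 fold change among passing genes of at least 5 CPM whose groups did not overlap, and in each list up to 4 passing members by smallest p and 2 others by highest level. Unnamed gene models were left out. The text gives only part of those named within lists.

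The tests were tried on simulated data, with counts drawn for the genes tested and 200 genes changed, in 5 runs of the knockout against heterozygous comparison. With on average 15852.6 genes tested, edgeR recovered 43.4% of genes changed by an absolute log2 fold change of 1 and 82.2% of those changed by 2, and 5.70% of its calls were false. Limma-voom recovered 41.6% and 79.6%, with 6.50% false. DESeq2 1.42.0 recovered 61.2% and 91.8% of changed genes among 16436 genes, with 31.6% false. These shares of false calls hold for 200 changed genes and for counts drawn with the dispersions that edgeR had estimated. Camera called a changed list in 5 of 5 runs and an unchanged list in 1 of 5. The genes were drawn independently of each other, so these runs do not show how camera behaves on lists with correlated members.

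The alternatives chosen before the data were examined were DESeq2, limma-voom, other scalings (RLE, upper quartile, library size), other filters (none, or 1 CPM in 2 samples), a replicate block, leaving out each sample, robust fitting, a minimum absolute log2 fold change of 1, an estimated correlation for lists, and 20 or 100 neighbours of Id3 on each side. Those added after the main values were seen were removal of mitochondrial and hepatocyte marker genes, the mean log2 CPM of hepatocyte markers as a covariate, and offsets for transcript length and GC content (loess in each library).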

Results

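Kupffer cells, the macrophages that reside in the liver sinusoids, were profiled by RNA sequencing from mice of 2 genotypes. Id3 encodes an inhibitor of DNA binding, a small helix-loop-helix protein that binds E proteins and keeps them off DNA. The study belongs to work on how resident macrophages acquire their tissue identity. The comparison asked which transcripts differ in Kupffer cells that lack Id3 (knockout, 2 samples, replicates 2 and 3) from those that keep 1 copy (heterozygous, 3 samples, replicates 1 to 3). Each library held 74.8M to 80.9M counts assigned to genes, with 20351 to 21187 genes detected. The 10 most abundant genes took 11.3% to 12.9% of the counts. Across genes, Pearson correlations of log2 CPM ran from 0.958 to 0.969 within a genotype and from 0.936 to 0.946 between genotypes. The first axis of a multidimensional scaling plot (43.9% of the variance) placed the heterozygous libraries between -1.27 and -1.08 and the knockout libraries at 1.71 and 1.79. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of 33.1 or more). The labels do not say that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

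Id3 transcripts (ENSMUSG00000007872.3, chromosome 4) were nearly gone from the knockout libraries. The heterozygous libraries held 229, 221 and 256 CPM, and the knockout libraries 1.01 and 1.42 CPM, from 76 and 110 counts. The knockout mean was 0.516% of the heterozygous mean, with a log2 fold change of -7.60 ± 0.20 (SE, n = 3 and 2, edgeR adjusted p = 0.000233). Each library thus matched its genotype label. Which part of the gene was removed is not given in the sources used here. Id1, a paralog that bone morphogenetic proteins also induce, was higher in the knockout cells, at 166 and 175 CPM against 39.9, 50.4 and 59.6 CPM (log2 fold change 1.77 ± 0.17, edgeR adjusted p = 0.0058). Id2 was also higher, with 387 ± 11.8 CPM (SD, n = 2) against 290 ± 3.29 CPM (SD, n = 3), a log2 fold change of 0.42 ± 0.08 (edgeR adjusted p = 0.0218). Id4 stayed low, at 1.83 CPM in the knockout and 1.89 CPM in the heterozygous cells, and did not pass the test (edgeR adjusted p = 0.954). Among the E proteins that Id proteins bind, Tcf3 rose by a log2 fold change of 0.78 ± 0.09, Tcf12 changed by -1.46 ± 0.23, and Tcf4 (-0.65 ± 0.22) did not pass. In the list of Id and E proteins, 3 of 7 genes were therefore higher and 2 lower, with 3 higher and 3 lower when adjusted over the list alone. The Id2 call was lost without heterozygous replicate 1 or 2 or without knockout replicate 2, and the Tcf12 call without heterozygous replicate 2 or knockout replicate 2.

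**Figure D1:**
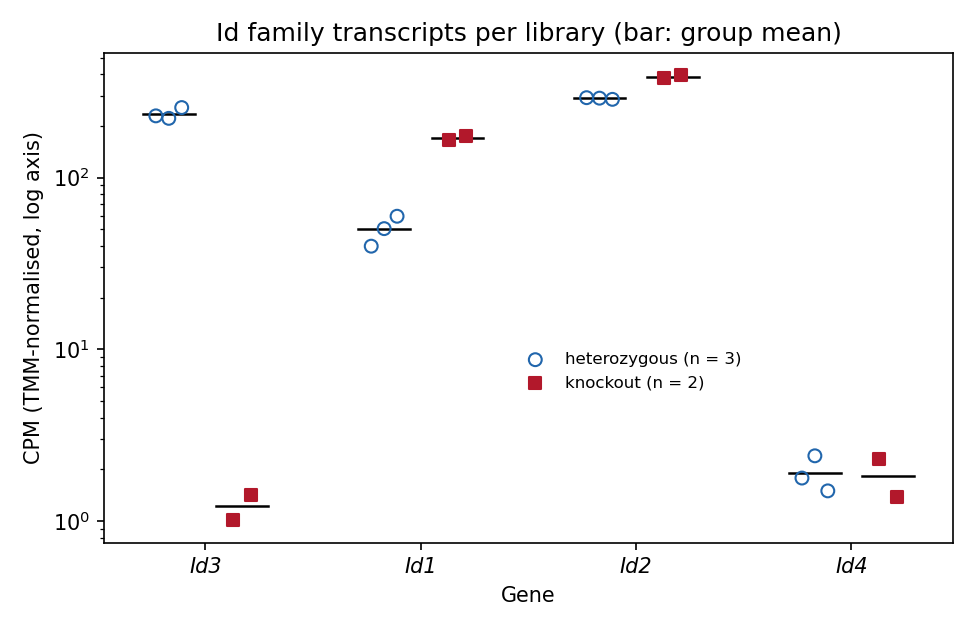
Normalised read count (CPM, log axis) of Id3, Id1, Id2 and Id4 in each of the 5 libraries, with open circles for the 3 heterozygous and filled squares for the 2 knockout libraries and a bar at each group mean. Id3 sat at 221 to 256 CPM in the heterozygous and 1.01 to 1.42 CPM in the knockout libraries, while Id1 sat at 39.9 to 59.6 and 166 to 175 CPM.

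Loss of Id3 went with changes in 2698 of the 16436 genes tested, of which 1054 were higher and 1644 lower in the knockout cells (edgeR quasi-likelihood test, adjusted p under 0.05). Of the 1267 with an absolute log2 fold change of at least 1, 219 were higher and 1048 lower. The excess of lower genes depended on the scaling. With no minimum fold, upper-quartile scaling gave 1443 higher and 1499 lower, RLE 1103 and 1583, and library size 1195 and 1555. The 2 genotypes did not overlap in 51.5% of the tested genes, where chance gives 20%. Short and GC-rich transcripts tended to be higher in the knockout libraries: the median log2 fold change was 0.21 in the shortest 25% of the transcripts and -0.31 in the longest 25%, and -0.44 and 0.27 in the 25% with the lowest and the highest GC content. With offsets for length and GC content, 1504 genes passed, 748 higher and 756 lower, and 1216 of them were among the 2698. The count fell to 463 without heterozygous replicate 1, to 335 without heterozygous replicate 2, to 903 without knockout replicate 2, and to 1 with the mean hepatocyte marker level as a covariate. Of the 102 genes named here as passing, 39 passed in each of the 5 fits that left out 1 library, and 0 changed sign in any of them. These 39 were Id3, Id1, Tcf3, Nr1d1, Trib3, Cd207, Il1b, Nr4a1, Il21r, Mup10, Mup3, Adamdec1, Ces3b, Ces3a, Ces1f, Ccr3, C9, Cyp2c40, Serpina1e, Cd163, Marco, Mrc1, Scd1, C4b, Cd300ld, Gbp2, Gbp3, Ifi205, Junb, Ier2, Dusp1, Fn1, Trf, Serpina3k, Fga, Dpp4, mt-Cytb, mt-Co1 and Hist1h1c. The call was lost by 44 of the 102 without heterozygous replicate 1, 63 without heterozygous replicate 2, 8 without heterozygous replicate 3, 35 without knockout replicate 2 and 7 without knockout replicate 3. With length and GC offsets 25 of the 102 lost it: Ngp, Rps3a3, Mup5, Tcf12, Tfec, Cebpb, Nr1h2, Grn, Hmox1, Cd86, Mcm4, Rrm2, Lamp2, Ctsz, Cox4i1, Ndufs1, Casp1, Cx3cr1, Fabp4, Cxcl13, Vcam1, Col3a1, Tbx21, Batf3 and Pf4. Among these, Tfec went to a log2 fold change of -0.04, Ndufs1 to -0.09, Cox4i1 to 0.18, Cd86 to -0.23 and Lamp2 to -0.24. Others lost the call with little change in value, such as Ngp (8.45 to 8.41), Rps3a3 (6.87 to 6.88) and Tbx21 (2.32 to 2.07). A lost call alone thus does not show that length or GC content accounts for a change. Of the 29 named genes that did not pass, 10 passed in at least 1 of these fits: Csf1r (0.38), Slc40a1 (0.36), Axl (0.45), Hspa8 (-0.51), Apoa1, Apoa2, Ltf, Ighm (1.01) and mt-Nd5 without knockout replicate 3, Apoa2 also without knockout replicate 2, and C1qa (0.36) without heterozygous replicate 3.

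The genes with the highest fold changes, taken by a rule fixed beforehand, included transcripts known from granulocytes and monocytes. S100a9 and S100a8, the subunits of calprotectin, rose by log2 fold changes of 6.76 ± 0.81 and 3.06 ± 0.53, to 22.8 ± 14.1 and 27.3 ± 16.1 CPM (SD, n = 2). Ngp, a neutrophil granule protein (8.45 ± 2.16), Rps3a3, a ribosomal protein copy (6.87 ± 1.62), and Ace, the angiotensin-converting enzyme (3.48 ± 0.82), owed their size to knockout replicate 2. Without it, their log2 fold changes were 2.06, 1.60 and 1.72 and none passed. Ngp had 0 counts in heterozygous replicates 1 and 3, so its fold rests on replicate 2 (0.329 CPM) there. Ly6c2, a monocyte surface antigen, rose by 4.69 ± 0.65. Its sequence is close to that of Ly6c1, and that of Rps3a3 to its copies, so both values are uncertain. Cd207, which encodes the lectin langerin and is known from Langerhans cells and Kupffer cells, had the smallest p after Id3: it rose from 167 ± 11.6 to 896 ± 2.96 CPM, a log2 fold change of 2.42 ± 0.09 (edgeR adjusted p = 0.00094). Il1b and Ccl4, an inflammatory cytokine and a chemokine, rose by 2.42 ± 0.21 and 2.36 ± 0.33. Nr4a1 and Dusp5, both induced by mitogenic signals, rose by 2.39 ± 0.19 and 2.98 ± 0.41. The remaining genes of the top 15 were Nr1d1, a repressor of the circadian clock (2.65 ± 0.22), Trib3 and Asns, targets of the amino acid stress factor ATF4 (2.47 ± 0.21 and 2.42 ± 0.34), and the cytokine receptor Il21r (2.17 ± 0.18).

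Genes with the lowest fold changes included transcripts that hepatocytes make in quantity. Mup5, a major urinary protein, had 0 counts in both knockout libraries and 8.99 ± 11.4 CPM (SD, n = 3) in the heterozygous ones, so it was at least 229-fold lower against a floor of 3 counts per library. Without heterozygous replicate 1 this bound fell to 61.1-fold, and the call was lost in 4 of the 5 fits that left out 1 library. Mup10 had 6 counts over the knockout libraries and 2123 over the heterozygous ones, a ratio of 231 (95% exact counting interval 106 to 631). Mup20 and Mup3 changed by log2 fold changes of -5.86 ± 0.77 and -5.18 ± 0.57. The carboxylesterases Ces3b, Ces3a and Ces1f changed by -5.09 ± 0.34, -3.93 ± 0.21 and -3.74 ± 0.36, and the cytochromes Cyp2c69 and Cyp2c40 by -3.97 ± 0.59 and -3.93 ± 0.49. Complement C9 (-4.05 ± 0.45), Serpina1e (-3.73 ± 0.46) and Selenbp2 (-3.61 ± 0.69) completed this group. Members of the Mup, Ces, Cyp2c and Serpina1 families share long stretches of sequence and the counting left out reads with several alignments, so their single values are uncertain. The 2 others besides Id3 were Adamdec1, a macrophage metalloprotease, which went from 35.1 ± 4.13 to 0.659 ± 0.201 CPM (log2 fold change -5.73 ± 0.26, edgeR adjusted p = 0.00163), and Ccr3, a chemokine receptor (-4.12 ± 0.25).

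Of 29 members measured of the Kupffer cell identity list, 3 were higher, 5 lower and 21 not called, with 4 higher and 9 lower when adjusted over the list alone. Over all genes tested, 2698 of 16436 passed, a smaller share than in this list. The members not called are therefore no sign of an unchanged identity. Besides Cd207, the scavenger receptor Marco rose from 1726 ± 219 to 3599 ± 86.9 CPM (log2 fold change 1.06 ± 0.12, edgeR adjusted p = 0.00768). The haemoglobin scavenger receptor Cd163 went from 472 ± 40.9 to 228 ± 15.2 CPM (-1.05 ± 0.11) and complement C6 changed by -0.76 ± 0.11. Clec4f, the lectin that marks Kupffer cells, was at 16780 ± 407 CPM in the heterozygous and 14615 ± 1462 CPM in the knockout cells (-0.20 ± 0.08, edgeR adjusted p = 0.153). Cd5l was at 8862 ± 935 and 11104 ± 1029 CPM (0.33 ± 0.11, edgeR adjusted p = 0.0971). Together the list held 5.15% of the counts in the heterozygous and 5.35% in the knockout libraries. Camera did not call the list (adjusted p = 0.585), and 19 of its 30 genes also stand in other lists. Fry, which tests whether members move on balance to 1 side, gave a lower direction (adjusted p = 0.0072). Its test for change in either direction gave an adjusted p of 0.000168, and many other lists also passed that one.

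Transcription factors of Kupffer cells gave 2 higher and 1 lower of 15 (3 and 3 adjusted over the list alone, camera adjusted p = 0.774). Cebpb rose by a log2 fold change of 1.00 ± 0.17 and Nr1h2 by 0.60 ± 0.11, Tfec changed by -0.68 ± 0.11, and Rxra (0.13 ± 0.09) and Irf7 (0.35 ± 0.30) did not pass. Of 28 genes shared by macrophages, 4 were higher and 4 lower (9 and 8 adjusted over the list alone, camera adjusted p = 0.774). Its median was above 0 (0.12) and its mean below (-0.10). Sirpa, which delivers an inhibitory signal on contact with CD47, rose by 0.60 ± 0.07 and the progranulin gene Grn by 0.55 ± 0.08. The mannose receptor Mrc1 changed by -1.36 ± 0.17. Csf1r, the receptor on which macrophage survival depends, was at 9228 ± 421 and 10353 ± 2251 CPM (0.17 ± 0.14, edgeR adjusted p = 0.45). Scavenger and engulfment receptors split into 3 higher and 5 lower of 25 (3 and 9 adjusted over the list alone, camera adjusted p = 0.353), with Cd300ld at -1.77 ± 0.14 and Axl at 0.26 ± 0.12, which did not pass. Of 18 genes of iron and haem handling, 5 were higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.235). The haem transporter Slc48a1 (0.91 ± 0.13), haem oxygenase Hmox1 (0.65 ± 0.13) and ferritin Fth1 (0.44 ± 0.08) rose, and the iron exporter Slc40a1 (0.29 ± 0.08) did not pass. Lysosomal genes gave 5 higher and 2 lower of 30 (13 and 5 adjusted over the list alone, camera adjusted p = 0.135), with Ctsz at 0.53 ± 0.09 and Lamp2 at -0.95 ± 0.14.

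Lipid genes moved in both directions. Among 15 LXR targets and lipid efflux genes, 3 were higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.311). Pltp, a phospholipid transfer protein, rose by a log2 fold change of 0.67 ± 0.07 and Lpcat3 by 0.54 ± 0.08, whereas the lipogenic enzymes Scd1 and Fasn changed by -1.28 ± 0.10 and -1.01 ± 0.14. Apoe was at 21101 ± 657 and 23196 ± 2097 CPM and did not pass. Nr1h3, the gene of LXR alpha, was at 831 ± 66.5 and 831 ± 107 CPM. Of 20 cholesterol synthesis genes, 1 was higher, 1 lower (Cyp51, -1.26 ± 0.21) and 18 were not called (camera adjusted p = 0.591, with 1 higher and 1 lower adjusted over the list alone). Complement genes gave 3 higher and 4 lower of 14 (6 and 6 adjusted over the list alone, camera adjusted p = 0.774). C3 and C4b, which hepatocytes also make, changed by -2.02 ± 0.27 and -1.01 ± 0.14 in libraries whose hepatocyte marker counts were also lower, while C1qa (0.29 ± 0.09) did not pass.

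Targets and receptors of the BMP and SMAD pathway, upstream of the Id genes, gave 6 higher and 3 lower of 15 (6 and 4 adjusted over the list alone, camera adjusted p = 0.774). Besides Id1 and Id2, the inhibitory Smad6 (log2 fold change 0.68 ± 0.11) and the receptor Tgfbr2 (0.42 ± 0.08) rose. The list's median was below 0 (-0.17) and its mean above (0.01).

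Immediate-early and inflammatory genes were higher in the knockout cells. Of 27 genes induced by stimulation or tissue dissociation, 15 rose and 1 was lower (15 and 2 adjusted over the list alone), with a median log2 fold change of 0.82. Camera called the list upward (adjusted p = 1.08e-05, but adjusted p = 0.533 with an estimated correlation). Junb, a subunit of the AP-1 factor, went from 121 ± 6.42 to 299 ± 18.8 CPM (log2 fold change 1.30 ± 0.09), Ier2 rose by 1.17 ± 0.10 and the phosphatase Dusp1 by 1.77 ± 0.17. The chaperone Hspa8 (-0.31 ± 0.13) and Rhob (0.32 ± 0.13) did not pass. Of 30 genes of the NF-kB inflammatory list, 11 rose and 0 were lower (14 and 0 adjusted over the list alone), with a median of 0.74 (camera adjusted p = 2.1e-05, and adjusted p = 0.533 with an estimated correlation). Beside Il1b and Ccl4, the costimulatory receptor Cd40 rose by 0.95 ± 0.12 and Nfkb2 by 0.74 ± 0.10, while the inhibitor Nfkbia (0.24 ± 0.11) and the antagonist Il1rn (-0.06 ± 0.09) did not pass. Summed neutrophil marker counts were also higher in these libraries.

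Interferon-induced genes that passed were lower, without a list call: 0 of 33 were higher and 8 lower (1 and 10 adjusted over the list alone, camera adjusted p = 0.0532, and adjusted p = 0.881 with an estimated correlation). The summed level of the list was 2726 to 3215 CPM in the heterozygous libraries, which knockout replicate 2 (2254 CPM) and knockout replicate 3 (4081 CPM) left on opposite sides. The guanylate-binding proteins Gbp2 and Gbp3 both changed by a log2 fold change of -1.52, with SE 0.13 and 0.17, Ifi204 by -2.76 ± 0.40 and Ifi205 by -3.54 ± 0.38. Irf7 and Bst2 (0.41 ± 0.20) did not pass. Of 19 cytokines and ligands that act on lymphocytes, 3 were higher and 3 lower (5 and 4 adjusted over the list alone, camera adjusted p = 0.453). Cxcl16 rose by 0.66 ± 0.08, Cxcl9 changed by -2.66 ± 0.51, and Il18 (-0.35 ± 0.11) and its binding protein Il18bp (0.24 ± 0.11) did not pass. Of 14 MHC class II and costimulatory genes, Cd40 was higher and Cd86 lower (-0.67 ± 0.15), with the same 1 and 1 adjusted over the list alone (camera adjusted p = 0.893). Cd74 was at 3010 ± 1069 and 1948 ± 233 CPM and did not pass. Among 24 apoptosis and survival genes, 6 were higher and 3 lower (9 and 6 adjusted over the list alone, camera adjusted p = 0.303), with Bcl2a1a at 1.42 ± 0.19, an uncertain value among its close paralogs, Casp1 at -0.84 ± 0.11 and Mcl1 at 0.17 ± 0.08, which did not pass. Of 37 cell cycle genes, 2 were lower, Mcm4 (-0.95 ± 0.14) and Rrm2 (-0.81 ± 0.17), and 1 was lower adjusted over the list alone (camera adjusted p = 0.217).

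Hepatocyte transcripts were lower in the knockout libraries. Of 25 markers, 17 were lower and 0 higher (18 and 0 adjusted over the list alone), with a median log2 fold change of -1.65 (camera adjusted p = 1e-07, and adjusted p = 0.881 with an estimated correlation). Their summed level was 31367, 34621 and 28103 CPM in the heterozygous libraries and 6036 and 14590 CPM in the knockout libraries, which is 3.14% and 1.03% of the counts on average. The fibrinogen chain Fga went from 1548 ± 157 to 199 ± 102 CPM (-2.96 ± 0.34), Serpina3k from 3119 ± 426 to 470 ± 211 CPM (-2.73 ± 0.30) and transferrin, Trf, from 1612 ± 65.7 to 796 ± 99.5 CPM (-1.02 ± 0.11). The apolipoproteins Apoa1 (-0.86 ± 0.37) and Apoa2 (-0.08 ± 0.38) did not pass, but Apoa2 passed at 0.47 without knockout replicate 2 (edgeR adjusted p = 0.0389) and at -0.99 without knockout replicate 3 (edgeR adjusted p = 0.00453). Apoa1 stood at -0.34 without knockout replicate 2 and passed at -1.70 without knockout replicate 3. The log2 ratio of the sums, -1.60, became -1.10 without knockout replicate 2 and -2.38 without knockout replicate 3.

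Neutrophil markers were higher, with 10 of 13 higher and 0 lower (11 and 0 adjusted over the list alone) and a median log2 fold change of 3.06 (camera adjusted p = 1.58e-05, and adjusted p = 0.718 with an estimated correlation). Their sum was 185, 193 and 166 CPM in the heterozygous and 610 and 314 CPM in the knockout libraries. Its log2 ratio of 1.35 fell to 0.79 without knockout replicate 2. The median of the list was 1.80 without knockout replicate 2, 4.59 without knockout replicate 3 and 1.45 with a filter of 1 CPM in 2 samples. Csf3r rose by 0.78 ± 0.13, while Retnlg (-0.07 ± 0.59) did not pass. Ltf, which did not pass either, was at 40.5 CPM in knockout replicate 2 and had 0 counts in knockout replicate 3, against 0 to 0.604 CPM in the heterozygous libraries. Markers of T and NK cells gave 3 higher of 21 (6 adjusted over the list alone) and a camera call upward (adjusted p = 0.00941, and adjusted p = 0.881 with an estimated correlation), with Cd4 at 0.79 ± 0.16 and Tbx21 at 2.32 ± 0.54. This call ended without heterozygous replicate 3 (adjusted p = 0.0713) and without knockout replicate 2 (adjusted p = 0.353), where Tbx21 stood at 1.54.

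**Figure D2:**
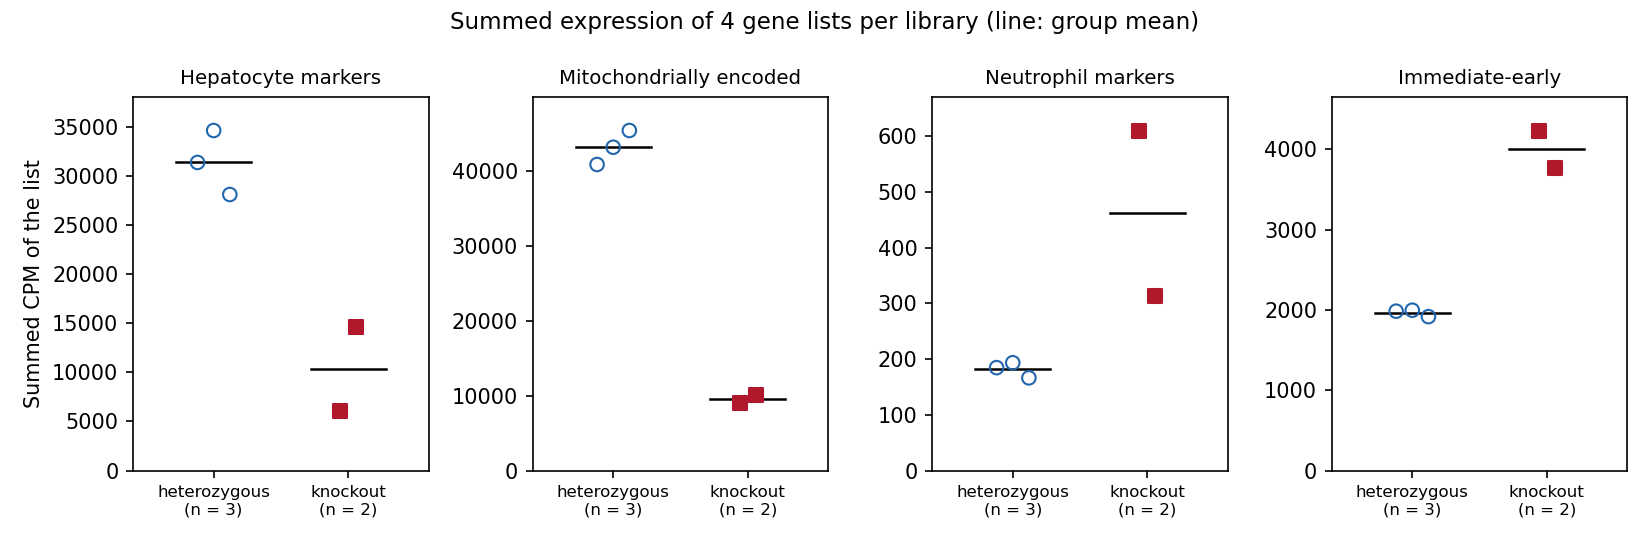
Summed normalised read count (CPM, axes from 0) of hepatocyte markers, mitochondrially encoded genes, neutrophil markers and immediate-early genes in each of the 5 libraries, with lines at the group means. Hepatocyte sums were 28103 to 34621 CPM in the heterozygous and 6036 and 14590 CPM in the knockout libraries, and mitochondrial sums 40819 to 45354 CPM and 9049 and 10112 CPM.

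Camera called no other cell type list. Of 24 sinusoidal endothelial markers, 1 was higher and 6 lower (1 and 7 adjusted over the list alone, camera adjusted p = 0.071), with Lyve1 at -2.20 ± 0.35 and the scavenger receptor Stab2 at 0.01 ± 0.10, which did not pass. Stellate cell and fibroblast markers gave 2 higher and 5 lower of 20 (3 and 9 adjusted over the list alone, camera adjusted p = 0.0887), among them Col3a1 at -0.87 ± 0.14, and fry passed this list downward (adjusted p = 0.000797). Of 19 monocyte markers, Ly6c2 was higher and Fn1 and Hp were lower, with the same counts adjusted over the list alone (camera adjusted p = 0.815). Fn1 and Hp, which hepatocytes secrete, changed by -2.10 ± 0.25 and -1.94 ± 0.31, alongside the hepatocyte markers. Dendritic cell markers gave 2 higher and 1 lower of 16, also when adjusted over the list alone (camera adjusted p = 0.774), with Dpp4 at -2.32 ± 0.28 and Batf3 at 0.78 ± 0.14. B cell markers gave 1 lower of 16 by either adjustment (camera adjusted p = 0.715), and Ighm (0.62 ± 0.29) did not pass. Erythroid markers gave 1 lower of 16 and 0 adjusted over the list alone (camera adjusted p = 0.815), with Hbb-bs, an uncertain value among the globin copies, at 1837 ± 201 and 1501 ± 226 CPM. Platelet markers gave 2 higher, among them Pf4 (0.55 ± 0.08), and 1 lower of 14 by either adjustment (camera adjusted p = 0.815). Of 10 cholangiocyte markers, the keratin Krt8, which hepatocytes also express, was lower (-2.06 ± 0.31) by either adjustment, alongside the hepatocyte markers (camera adjusted p = 0.692), and of 10 stem and progenitor markers, Erg was lower (-2.08 ± 0.43) by either adjustment (camera adjusted p = 0.699). The 3 mast cell, basophil and eosinophil markers measured were not called, and that list was too short for camera.

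Genes that mark macrophages of other tissues were not called as lists either. Microglial genes gave 2 lower of 15 by either adjustment (camera adjusted p = 0.893), P2ry12 at -2.03 ± 0.28 and Cx3cr1 at -0.84 ± 0.19. Alveolar genes gave 2 higher and 2 lower of 15, also when adjusted over the list alone (camera adjusted p = 0.815), with Fabp4 at -1.14 ± 0.17 and Marco higher. Peritoneal genes gave 1 higher and 1 lower of 16 (1 and 0 adjusted over the list alone, camera adjusted p = 0.568), Selp at 2.37 ± 0.41 and Cxcl13 at -1.21 ± 0.30. Splenic red pulp genes gave 2 higher and 4 lower of 14 (6 and 4 adjusted over the list alone, camera adjusted p = 0.699), with Vcam1 from 1343 ± 259 to 608 ± 18.6 CPM (-1.14 ± 0.17).

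Transcripts encoded in mitochondria were lower in both knockout libraries, with sums of 9049 and 10112 CPM against 40819, 43122 and 45354 CPM. Of 20 measured, 15 were lower and 0 higher by either adjustment, with a median log2 fold change of -2.03 (camera adjusted p = 3.22e-12, and adjusted p = 0.718 with an estimated correlation). The cytochrome b gene mt-Cytb went from 6814 ± 614 to 829 ± 158 CPM (-3.04 ± 0.16) and mt-Co1 from 13041 ± 2178 to 2511 ± 19.7 CPM (-2.38 ± 0.16), while mt-Nd5 (-0.91 ± 0.50) did not pass but stood at -0.26 without knockout replicate 2 and passed at -2.15 without knockout replicate 3. Nuclear genes of oxidative phosphorylation did not share this: 4 of 37 were higher and 1 lower (3 and 1 adjusted over the list alone), with a median of 0.19 and a camera call upward (adjusted p = 0.00768, and adjusted p = 0.881 with an estimated correlation). Cox4i1 rose by 0.55 ± 0.10 and Ndufs1 changed by -0.44 ± 0.10. Ribosomal protein genes had 2 higher and 2 lower of 83 (0 and 2 adjusted over the list alone), a median of 0.22 and a camera call upward (adjusted p = 0.0015, and adjusted p = 0.881 with an estimated correlation). Rpl4 (-0.59 ± 0.09) and Rpl34 (-0.90 ± 0.16) were the most significant members, against the direction of the list. The ribosomal call ended with length and GC offsets (adjusted p = 0.545) and without knockout replicate 3 (adjusted p = 0.0683), where the oxidative phosphorylation call also ended (adjusted p = 0.0895). Of 29 histone genes, Hist1h1c rose (1.24 ± 0.08) by either adjustment and 28 were not called (camera adjusted p = 0.893).

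**Figure D3:**
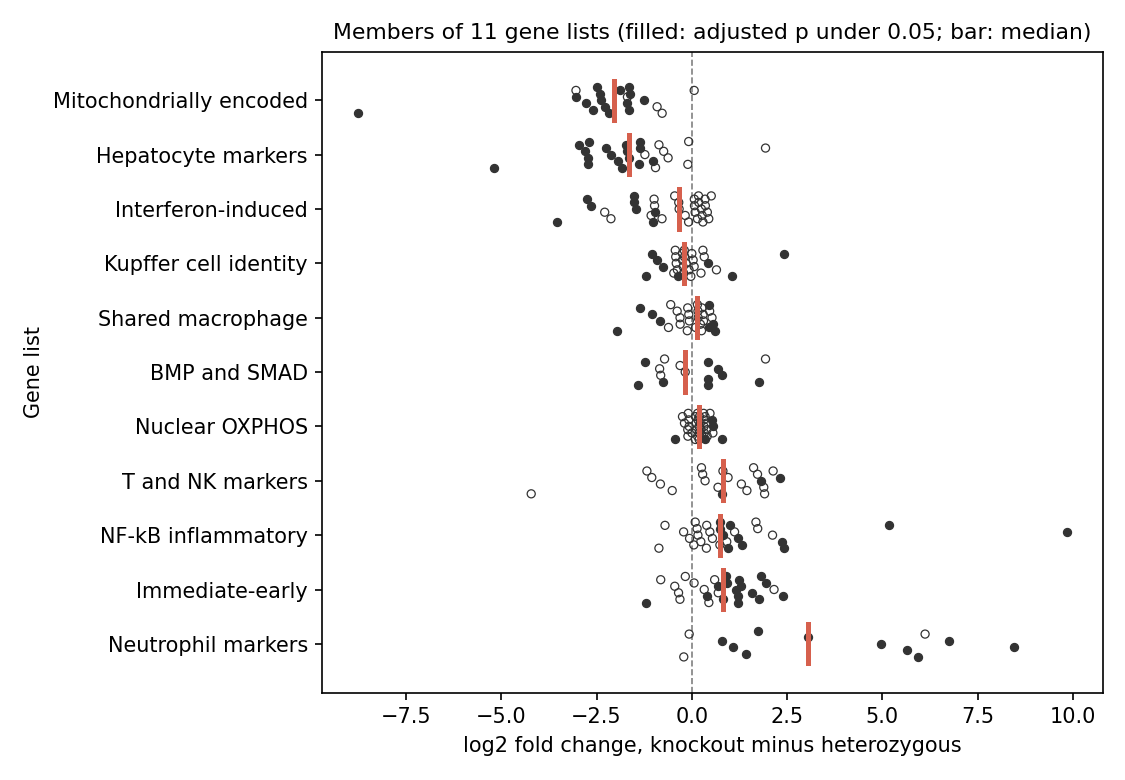
Log2 fold change (knockout minus heterozygous) of every measured member of 11 gene lists, with filled points for genes that passed the edgeR test, open points for those that did not, and a bar at each list's median. The medians were -2.03 for mitochondrial, -1.65 for hepatocyte, 0.82 for immediate-early, 0.74 for NF-kB inflammatory and 3.06 for neutrophil genes, and -0.20 for the Kupffer cell identity list (1 inflammatory gene had 0 counts in the heterozygous libraries, so its fitted position is no measure of its fold).

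All 5 libraries carried Y-linked transcripts, with 48 to 246 counts of Ddx3y, and 0 to 4 counts of Xist, so all came from males as far as these genes show. The 4 sex-linked genes measured were not called, by either adjustment (camera adjusted p = 0.12). Genes next to Id3 on chromosome 4 were called about as often as others: 17 of the 100 nearest tested genes passed, against 16.4% of the rest (odds ratio 1.04, 95% confidence interval 0.579 to 1.78, two-sided Fisher's exact test p = 0.892).

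Across the 39 lists tested, camera with its preset correlation called 8, of which 6 were upward and 2 downward, and with an estimated correlation 0 (lowest adjusted p = 0.533, with 2 lists at an unadjusted p under 0.05). The estimate was high for some lists (0.918 for hepatocyte markers). For immediate-early genes it was 0.027, yet the unadjusted camera p went from 8.28e-07 to 0.0241. For stellate cell markers it was -0.048, and the unadjusted camera p went from 0.025 to 0.0921. The few degrees of freedom of that run thus limit it, and its lost calls do not by themselves show an effect of correlation between genes. Fry passed 8 lists, namely mitochondrial, immediate-early, inflammatory and neutrophil genes, Id and E proteins, Kupffer cell identity, stellate cell markers and survival genes. Camera did not call the list of Id and E proteins (adjusted p = 0.884). Median, mean and camera direction did not share a sign in the lists of Kupffer cell transcription factors, shared macrophage genes, BMP and SMAD genes, splenic red pulp genes, histones, and markers of B cells, dendritic cells, platelets and cholangiocytes.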

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

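The alternatives added after the results were seen were the hepatocyte covariate, the length and GC offsets and the removal of mitochondrial and hepatocyte genes. The log2 fold change of Id3 stayed between -7.86 and -7.00 and past the threshold in every alternative run. Of 2698 genes changed, other scalings, limma-voom, robust fitting, other filters and the removal of mitochondrial and hepatocyte genes gave 2282 to 3497. DESeq2 gave 4629 (2653 shared). Its 31.6% of false calls on simulated data came with 200 changed genes. That share depends on how many genes change, so it cannot be carried over to this count. A minimum absolute log2 fold change of 1 left 1267, by its construction. Leaving out 1 sample gave 335 to 2540, with fewer samples and, where 1 knockout sample was left, the lone sample assumed to vary like the heterozygous ones. With length and GC offsets 1504 passed, and 50 of the 2698 changed sign. The hepatocyte covariate left 1 gene by edgeR (2100 at an unadjusted p under 0.05). It follows genotype closely (correlation -0.90), so little of the genotype difference is left to test. Beyond what is said here, the cause was not tested.

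The gene list tests called 8 lists, 13 with DESeq2 and 0 with an estimated correlation, and 6 to 11 in the other alternatives. With the hepatocyte covariate the T and NK cell list turned to a median of -0.58, Ngp to -4.13, Rps3a3 to -3.78 and Ace to -0.62. Apoa2, which did not pass with all samples, ran from -0.99 without knockout replicate 3 to 0.47 without knockout replicate 2, and passed in both. The hepatocyte list (median -0.19, adjusted p = 0.740) and the neutrophil list (median 0.31, adjusted p = 0.193) lost their call with the covariate, the former by construction since the covariate is made of its members, and the medians of the oxidative phosphorylation and ribosomal lists rose to 0.36 and 0.41. The neutrophil median was 1.45 with the 1 CPM filter, and the ribosomal one 0.11 with length and GC offsets. For the others the cause was not tested. Of the 102 named genes that passed, 101 lost the call with the covariate, 25 with length and GC offsets, 4 with limma-voom and 1 each with DESeq2, library size scaling and no filter. Of 29 that did not pass, 5 passed with DESeq2, and Slc40a1 also with limma-voom, upper-quartile and library size scaling, the 1 CPM filter, the offsets and the removal of mitochondrial and hepatocyte genes. Leaving out 1 sample moved the log2 ratio of the sums to between -2.38 and -1.10 for hepatocyte markers, -2.25 and -2.09 for mitochondrial genes and 0.789 and 1.75 for neutrophil markers. The odds ratio of calls near Id3 was 1.70 with 20 neighbours on each side (two-sided Fisher's exact test p = 0.138) and 1.16 with 100 (two-sided Fisher's exact test p = 0.442).

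With a replicate block, edgeR called 1 gene, with 3497 at an unadjusted p under 0.05, and 101 of the 102 named genes lost the call. Whether the 2 numbers the genotypes share pair the samples cannot be told. Deviations of same-numbered samples from their group means correlated at -0.026 and -0.062. With 2 knockout libraries those deviations mirror each other, so they cannot decide this. The block left 1 residual degree of freedom, so the lost calls say little about the size of the effects.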

Other observations

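The gene lists of this part were written after the results were seen, as were the tests on the lower hepatocyte share, reads with several alignments, hepatocyte RNA beside mitochondrial genes, neutrophils, tissue handling and other splits of the samples, while the tests on liver maturity, length and GC content and time of day were written before their results were seen.

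Targets of ATF4, the factor of amino acid stress, were higher in the knockout cells: of 19, 10 rose and 0 were lower, with a median log2 fold change of 0.74 (camera adjusted p = 4.2e-06 over 5 added lists, and adjusted p = 0.0507 with an estimated correlation). Trib3 and Asns had led to this list, and without them 8 of 17 rose, with a median of 0.70 (camera adjusted p = 6.94e-05). The list was written after the results were seen, and Cebpb (1.00), named above, stays in it, so this is no independent evidence. Beside Trib3 and Asns, the serine synthesis genes Phgdh and Psat1 rose by 1.74 and 0.74, the amino acid transporter genes Slc7a5 and Slc3a2 by 0.89 and 0.70, and Sesn2 by 0.83. The list was not uniform: 16 of the 19 had values above 0, and 9 were not called. Atf5 (-0.64), Chac1 (-0.25) and Slc7a11 (-0.02) lay below 0, and Ddit3 (0.61) and Shmt2 (0.03) did not pass either. Clock genes moved in both directions. Of 10 genes in a day-phase list, 3 were higher (Nr1d1 2.65, Dbp 2.13 and Tef 1.01), with a median of 0.84 (camera adjusted p = 0.0042, and adjusted p = 0.0701 with an estimated correlation). In all, 7 of the 10 had values above 0. Per3 (1.83), Ciart (1.83), Per1 (-0.16), Per2 (-0.28) and Nr1d2 (-0.19) did not pass. Members of this list may peak at different hours. Nr1d1 had led to the clock lists, and without it 2 of 9 were higher, with a median of 0.67 (camera adjusted p = 0.0163). This too is no independent evidence. Of 6 genes of the opposite phase, 3 were lower, among them Arntl (-1.05) and Cry1 (-1.25), with a median of -1.15 (camera adjusted p = 0.00245, and adjusted p = 0.0701 with an estimated correlation).

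Several abundant macrophage transcripts outside the lists changed, and were picked here after their values were seen. Cd83 went from 103 to 404 CPM (log2 fold change 1.97, edgeR adjusted p = 0.00223), Arg2 rose by 1.70, Capg by 1.63 and Coro1a by 1.24, and the endoplasmic reticulum chaperone gene Hspa5 changed by -1.39. These 5 passed in each of the 5 fits that left out 1 library and with length and GC offsets. The fifth added list, of major urinary proteins, had 6 of 9 lower and 0 higher (median -5.86, camera adjusted p = 2.3e-06, and adjusted p = 0.0507 with an estimated correlation), but it was chosen from members already named, so this is no independent evidence.

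Hepatocyte transcripts were lower in the knockout libraries, and 3 explanations were tested. If hepatocytes alone made these markers, a single lower share of hepatocyte RNA would lower all of them alike. Instead, the SD over markers of the log2 ratio to the heterozygous mean was larger in both knockout libraries. It was 4.69 times as large in the less spread knockout library as in the most spread heterozygous one (3.97 times with length and GC offsets). That mean includes the heterozygous libraries themselves, which makes their SD smaller, so these ratios are overstated. A lower share with another source of some markers is not excluded. Fga was at 127 and 272 CPM against 1410 to 1719 CPM, while Apoa2 was at 484 and 1347 CPM against 953 to 982 CPM. Length and GC content do not account for the whole pattern, since 88.2% of the called markers still passed with offsets (median -1.52, from -1.65). Less mature livers cannot be told apart from a genotype effect. The 8 perinatal liver genes had a median of 0.084 with a spread of 0.47 (0 higher and 1 lower, Mest at -1.14). Apart from Cd24a and Mest, their heterozygous means were only 0.122 to 2.64 CPM, so this median could show little either way. Hepatocytes that express the hepatocyte markers less without Id3, with or without a smaller share of their RNA, may remain as an untested explanation.

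Mitochondrial transcripts were lower in both knockout libraries. Mitochondrial RNA that came with hepatocyte RNA is argued against as the whole cause by the knockout libraries, where 25 of 25 hepatocyte markers were higher in replicate 3 than in replicate 2 by a median log2 ratio of 1.32 (SD 0.33), while 17 of 20 mitochondrial genes were higher by a median of 0.17 (SD 0.68). With the hepatocyte level, which follows genotype, as a covariate the median was -1.68 (spread over genes 0.38), from -2.03 (spread 0.39), and camera called the list lower (adjusted p = 1.34e-06, but adjusted p = 0.804 with an estimated correlation), while edgeR called 0 single genes (9 at an unadjusted p under 0.05). Length and GC content were argued against as the whole cause by the 93.3% of called genes that still passed with offsets (median -1.65, from -2.03). Reads moved to those with several alignments cannot be told apart from a genotype effect. Their share was lower in the knockout libraries (highest knockout minus lowest heterozygous -4.15 percentage points), but it is not split by origin. The missing mitochondrial reads would be 1.96% and 2.11% of the aligned total, which may count a read at each of its alignments. Reads moved in this way, a part carried by hepatocyte RNA and an effect of Id3 loss may therefore remain.

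Immediate-early and inflammatory genes were higher in the knockout cells. Neutrophils are only weakly argued against as the whole cause. The neutrophil list rose by 427 and 126 CPM in the knockout libraries (S100a8 and S100a9 by 67.9 and 25.2 CPM of this) against 3259 and 2448 CPM for the called members of both lists, a fraction of at most 0.131. Those members were chosen by their rise in these data, which lowers the fraction. How much of their RNA a neutrophil holds is also not known here. Stress of tissue handling cannot be told apart from a genotype effect, as the 6 heat-shock members had a median of -0.33, with Dnajb1 higher (0.39) and Hsph1 lower (-1.19). Collection at another time of day is a candidate explanation. The opposite-phase clock genes had a median of -1.15 with a spread of 0.23, and 0 of 6 were above 0. Of the 10 genes of the day-phase list, 7 were above 0 and 3 of them passed. Per1, Per2 and Nr1d2 (-0.19) were below 0 and did not pass. Members of that list may peak at different hours, so Per1 and Per2 do not decide this. Nr1d2 did not follow Nr1d1 (2.65). It ran from 2.09 to 8.22 CPM over the heterozygous libraries, so it does not decide this either. An effect of Id3 loss on the immediate-early and inflammatory genes, or on the clock genes themselves, stays open and untested.

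The 5 samples can be split into 3 and 2 in 10 ways, too few for a share under 0.05. The real split gave 2698 genes, as the 1 split with so many, and the highest of the other splits 0 (edgeR and limma-voom both 0, with 2287 at an unadjusted p under 0.05 by edgeR in the split of heterozygous replicates 1 and 2 from the rest). Every other split put libraries of both genotypes into the same group, where the genotype difference adds to the spread. Their 0 calls are therefore no measure of how often false calls arise.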
